A study of Mus musculus with 2 samples.

How the data were processed

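Cells of the E11.5 mouse lambdoid junction were measured by single-cell RNA sequencing in 2 libraries, a wild-type and a Crect; ROSA26-lacZ library. Both are labelled C57BL/6J. Each pooled the trypsin-dissociated tissue of 4 to 5 embryos. The deposited values are raw counts of UMIs per gene and cell barcode, without normalization. The submitters' processing notes name Cell Ranger 2.0 and build mm10, and the kit is the 10x Genomics 3' v2 kit per the labels. How barcodes were filtered and how strand was treated is not given in the sources used here. The gene tables hold 27998 genes, and that of the Crect lacZ library has 2 more entries, a Cre and a lacZ transgene. Gene locations and types came from GENCODE vM21, in which 27645 gene IDs (98.74%) were found.

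The comparisons, gene lists, class markers and most alternatives were chosen before the data were examined. Cells were kept with 500 or more genes and at most 10% of UMIs from mitochondrial genes. No barcode fell below the gene minimum, and 57 wild-type and 207 Crect lacZ barcodes were above the mitochondrial limit. Doublets were scored with Scrublet in scanpy 1.11.5 at an expected rate of 0.06. Its automatic threshold removed 170 wild-type barcodes (2.149%). In the Crect lacZ library it found only 2 (0.03%), under the 0.5% minimum set for a working threshold, so the 369 highest scores were removed, a share set by the number of barcodes. The cells kept held 121213067 wild-type and 115498250 Crect lacZ UMIs.

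Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, with the genes of the lists held out, were turned into z-scores within each library and reduced to 30 principal components. Clusters came from 15 neighbours and the Leiden algorithm at resolution 1.0 (leidenalg 0.10.2, python-igraph 0.11.9). Ectoderm-like and mesenchyme-like cells were clustered again with 20 components, S and G2/M scores regressed out and resolution 0.8. Clusters were named from marker lists for mesenchyme, ectoderm, endothelium, erythroid cells, macrophages, megakaryocytes, crest glia, neurons, skeletal muscle, mural cells, pigment cells, lens and retina. Lists for periderm, olfactory, basal surface, oral, maxillary (Lhx6, Lhx8, Barx1, Dlx1, Dlx2), nasal (Pax3 and Pax7 among others) and chondrogenic cells named the sub-clusters. The way marker scores were turned into names was fixed after the data were seen.

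For 5 comparisons of classes, raw counts were summed per library and class, giving 4 sums each. The comparisons used edgeR 4.0.16 (TMM scaling, filterByExpr, quasi-likelihood test) in R 4.3.3, with library as a block and Benjamini-Hochberg adjustment over 15202, 12214, 12092, 13677 and 14717 genes for ectoderm, periderm, olfactory, maxillary and endothelium. A call needed an adjusted p under 0.05 and a fold of 2 or more. Counts of calls and gene lists leave out class markers and genes used for clustering. Each fit had 1 residual degree of freedom, so spread was borrowed across genes, and the common biological coefficients of variation were 0.0679, 0.0766, 0.1197, 0.0308 and 0.0615. The prior degrees of freedom were infinite for periderm and endothelium. There the spread came from all genes alone, and p-values do not measure how far a single gene differed between the libraries. On simulated data with 200 changed genes, 72%, 55%, 50%, 82% and 71% of 2-fold changes were recovered, and 95%, 84%, 79%, 93% and 83% of 4-fold changes. Recovery here meant an adjusted p under 0.05 with the right direction, without the fold threshold, so fewer 2-fold changes would pass the call.

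There were 17 gene lists: Wnt, Fgf, Hedgehog, Bmp and Tgf-beta, retinoic acid and Notch pathways, ephrins and Eph receptors, orofacial clefting, adhesion and epithelial-mesenchymal transition, matrix and basement membrane, facial patterning factors, apoptosis, S phase, G2 and M phase, cyclin-dependent kinase inhibitors, dissociation response and sex-linked genes. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation. Genes were named by a rule: for each list in order, up to 2 genes per direction with the largest called change, the same sign in both libraries and a mean of 20 CPM or more, until 30 genes were reached. Between the libraries, sex-linked genes and transgenes were named, then the 5 largest ratios each way among genes with 100 or more UMIs and a ratio of 2 or more in both mesenchyme and ectoderm. Other genes are said to be named after their values were seen. Some genes that the rule named are left out of the text and the plots.

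No test was made between the genotypes, since each has 1 library. Ratios of CPM carry exact 95% Poisson intervals and shares of cells exact Clopper-Pearson intervals (scipy 1.17.1), which cover counting error only. Shares of cells with a transcript were computed after thinning each cell to 3000 UMIs. Where a bound is given for a count of 0, it uses a floor of 3 UMIs, and ratios of thinned cells have no floor and no interval. No paired analysis of the genotypes was possible because each was a single pool of embryos. Alternatives were DESeq2 1.42.0, no low-count filter, no library block, all classes in 1 fit, equal numbers of cells, doublets kept, a lower and a higher gene minimum, joint z-scores, resolutions 0.5 and 2.0, sub-cluster resolution 0.4, no regression of cell cycle scores, lists allowed as clustering features, TMM-scaled CPM, thinned and unthinned counts, and each library alone. Leaving out clusters of low UMI counts, chondrogenic-like cells or olfactory-like cells was chosen after seeing the data.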

Results

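Single-cell RNA sequencing was used to profile the E11.5 mouse lambdoid junction, the tissue at which the nasal prominences touch the maxillary ones and in which the upper lip and primary palate fuse. There were 2 libraries, 1 per genotype: wild-type C57BL/6J embryos, and embryos carrying Crect, an ectodermal Cre recombinase transgene, together with a lacZ reporter at the ROSA26 locus. Each library was made from the pooled tissue of 4 to 5 embryos, so a value within a library is an average over a pool, and no difference between the genotypes has a replicate check. The wild-type library held 7966 barcodes and 126638790 unique molecular identifiers (UMIs), with a median of 14055.5 UMIs and 3945.5 genes per barcode. The Crect lacZ library held 6894 barcodes and 127765199 UMIs, with medians of 17293 UMIs and 4216 genes. The study states about 8000 and about 7000 cells. After the filters on mitochondrial share and doublets, 7739 wild-type and 6318 Crect lacZ cells were kept, with medians of 13964 and 17272 UMIs.

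The first question was which tissues the dissected region held and in what proportion. Most cells were mesenchyme-like, with high Prrx1, Twist1, Col3a1 and Col1a2, and they made up 79.5% of wild-type cells (6150 cells, 95% exact Clopper-Pearson interval 78.6 to 80.4) and 83.1% of Crect lacZ cells (5253 cells, 82.2 to 84.1). Ectoderm-like cells, with Epcam, Krt14, Krt18 and Trp63 among their leading genes, made up 12.9% (995 cells, 12.1 to 13.6) and 11.8% (747 cells, 11 to 12.6). Endothelium-like cells with Cdh5, Kdr and Cldn5 made up 2.79% (216 cells, 2.44 to 3.18) and 1.87% (118 cells, 1.55 to 2.23), and erythroid-like cells led by globin genes made up 3.00% (232 cells, 2.63 to 3.4) and 2.15% (136 cells, 1.81 to 2.54). Macrophage-like cells, whose leading genes C1qa, C1qb and Tyrobp stood beside the platelet genes Pf4 and Ppbp, made up 0.827% (64 cells) and 0.459% (29 cells). With doublets kept their shares were 0.809% (64 cells) and 0.703% (47 cells). The rule for removing doublets differed between the libraries, so the gap between these shares depends on it. Neural crest glia-like cells with Sox10 and Fabp7 made up 0.388% and 0.348%. These intervals cover counting error only. No cluster took its name from the neuron, skeletal muscle, mural, pigment, lens, retina or megakaryocyte markers. A sub-cluster of 52 wild-type (0.672%) and 13 Crect lacZ cells (0.206%) that held ectodermal cells with mesenchymal leading genes was taken out of the ectoderm after the data were seen.

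**Figure D1:**
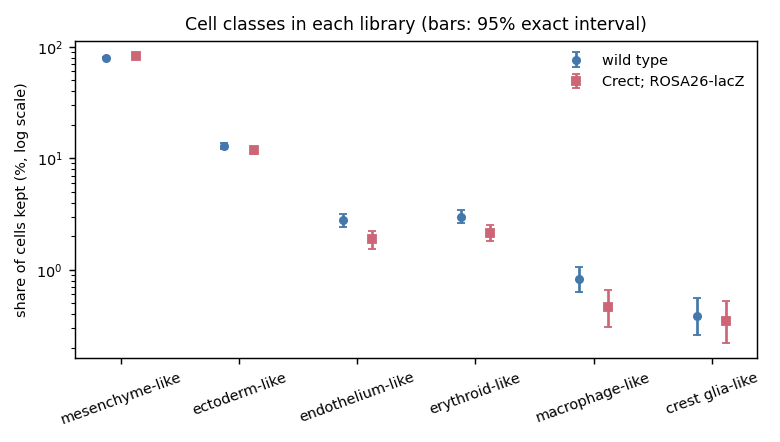
Share of the cells kept (percent, log axis) in each of the 6 named classes, for the wild-type (circles) and the Crect; ROSA26-lacZ library (squares), with 95% exact binomial intervals that cover counting error only. Mesenchyme-like cells made up 79.5% and 83.1%, and ectoderm-like cells 12.9% and 11.8%.

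Within the ectoderm, 5.53% of wild-type (55 cells, 4.19 to 7.13) and 4.42% of Crect lacZ ectoderm-like cells (33 cells, 3.06 to 6.15) were periderm-like, the flat outer layer with Gabrp and Emp1 among its leading genes. Sub-clusters were also named basal surface-like (35.9% and 20.3%) and oral-like (18.5% and 16.2%), and 36.6% and 48.3% of ectoderm-like cells stayed unnamed. An olfactory-like sub-cluster held 35 wild-type and 80 Crect lacZ cells. Its olfactory markers stood at a mean of 0.956 of their highest level in any ectodermal sub-cluster. Of its 10 leading genes, 6 were neuronal markers such as Tubb3, Stmn2 and Elavl4. Whether it is 1 cell type or a mixture was not resolved, so its share is not read as one of olfactory epithelium alone. Within the mesenchyme, maxillary-like cells, with Shox2, Osr2 and Lhx6 among their leading genes, made up 10.4% (640 cells, 9.65 to 11.2) and 8.70% (457 cells, 7.95 to 9.49). The size of this class depended on the setting, with 407 and 383 cells without regression of cell cycle scores, 482 and 397 at sub-cluster resolution 0.4 and 770 and 504 with the gene lists among the clustering features. Nasal-like cells, named by their scores for markers that included Pax3 and Pax7, numbered 3127 and 2535, and 38.3% and 33% of mesenchyme-like cells stayed unnamed. A chondrogenic-like sub-cluster with Sox9 and Col9a1 made up 0.439% of wild-type (27 cells, 0.290 to 0.638) and 10.1% of Crect lacZ mesenchyme-like cells (529 cells, 9.27 to 10.9), and with 1 library per genotype its origin was not resolved. Clusters with low UMI counts held part of the unnamed cells in both tissues.

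The ectoderm and the mesenchyme that face each other at the fusion site were compared within each library. The Wnt ligands Wnt3 and Wnt6 were 92.2-fold (95% interval 76.3 to 112) and 56.9-fold (49.8 to 64.9) higher in ectoderm-like than in mesenchyme-like cells in both of 2 libraries (adjusted p = 1.2e-11 and 5.61e-12, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The Fgf ligands Fgf9 and Fgf17 were 72.1-fold (60 to 86.8) and 66.7-fold (51.1 to 87.2) higher (adjusted p = 1.52e-11 and 1.94e-10). Mesenchyme-like cells had more of the Wnt agonists Rspo2 and Rspo3, which were 14-fold (12 to 16.5, adjusted p = 1.16e-10) and 13-fold (11.1 to 15.2, adjusted p = 1.69e-10) lower in ectoderm. The receptor gene Fgfr1 was 3.51-fold lower in ectoderm (3.14 to 3.91, adjusted p = 2.77e-09). Aldh1a3, a retinoic acid synthesis enzyme, was 46.1-fold higher in ectoderm (39.7 to 53.5, adjusted p = 7.29e-12). The retinoic acid receptor gene Rarb was 6.24-fold (5.24 to 7.43, adjusted p = 6.35e-09) and the binding protein gene Crabp1 4.66-fold (3.74 to 5.81, adjusted p = 2.04e-07) lower. The tight-junction genes Cldn3 and Cldn4 were 91.6-fold (73.4 to 114) and 64.9-fold (54.1 to 77.9) higher in ectoderm. The repressors of epithelial genes Zeb2 and Zeb1 were 15.5-fold (13.4 to 17.9) and 10.7-fold (8.36 to 13.6) lower. Wnt3 (ENSMUSG00000000125) lies on chromosome 11 from 103774150 to 103817957 and Zeb2 (ENSMUSG00000026872) on chromosome 2 from 44983632 to 45117395 (build mm10). In all, 1600 genes were called higher and 910 lower in ectoderm.

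By group, 22 of 53 Wnt pathway genes tested rose and 17 fell in ectoderm, with 14 not called (22 and 18 adjusted over the list alone, camera adjusted p = 0.0566). Of 28 Fgf pathway genes, 13 rose and 5 fell (13 and 5 adjusted over the list alone), and the list was higher in ectoderm (camera adjusted p = 9.35e-05, adjusted p = 0.52 with an estimated correlation). Notch pathway genes were mostly ectodermal: 10 of 16 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 1.98e-05, adjusted p = 0.52 with an estimated correlation). The receptor gene Notch1 was 9.63-fold higher (8.32 to 11.1, adjusted p = 2.12e-10) and the feedback regulator gene Nrarp 34-fold higher (27.7 to 41.7, adjusted p = 9.49e-11). The transcriptional repressor gene Hey2 was 9.30-fold lower (7.63 to 11.3, adjusted p = 3.41e-09). Of 14 Hedgehog pathway genes, 2 rose and 5 fell, the co-receptor gene Gas1 by 2.14-fold (1.91 to 2.39), and of 37 Bmp and Tgf-beta genes 4 rose and 11 fell. Both lists were lower in ectoderm (camera adjusted p = 0.00427 and 0.0495, adjusted p = 0.52 for each with an estimated correlation), with the same counts adjusted over the list alone. Retinoic acid genes split (3 of 15 rose, 5 fell, adjusted p = 0.37), as did ephrins and Eph receptors (5 of 20 rose, 6 fell, adjusted p = 0.562), with Epha3 10.1-fold (8.76 to 11.8) and Efnb1 3.90-fold (3.45 to 4.40) lower in ectoderm.

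Genes linked to orofacial clefts lay on both sides of the fusion site: 14 of 36 rose in ectoderm and 8 fell (the same adjusted over the list alone, camera adjusted p = 0.0011, adjusted p = 0.52 with an estimated correlation). Ripk4, a kinase gene needed for epidermal differentiation, was 46.8-fold higher (37.2 to 58.9, adjusted p = 1.15e-10). Of 39 adhesion and epithelial-mesenchymal transition genes, 16 rose and 13 fell (the same adjusted over the list alone), and the list was higher in ectoderm (camera adjusted p = 3.46e-06, adjusted p = 0.52 with an estimated correlation). Matrix and basement membrane genes split (17 of 52 rose, 21 fell, adjusted p = 0.165), with the laminin receptor subunit gene Itga3 30.1-fold higher (24 to 37.8). Facial patterning transcription factors split as well (16 of 66 rose, 24 fell, adjusted p = 0.562). Named after their values were seen, Tfap2b was 53.2-fold (40.7 to 69.7) and Sp8 49-fold (38.5 to 62.4) higher in ectoderm, and Shox2 was 15.1-fold (12.2 to 18.7) and Gsc 10.7-fold (9.04 to 12.6) lower.

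Cell cycle genes differed little in size: 0 of 42 S phase and 0 of 52 G2 and M phase genes passed the 2-fold call with edgeR or with DESeq2, while 34 and 45 of them were lower in ectoderm and 3 and 1 higher at an unadjusted p under 0.05. Both lists were lower in ectoderm (camera adjusted p = 0.00427 and 9.35e-05, adjusted p = 0.627 and 0.52 with an estimated correlation). Of 7 cyclin-dependent kinase inhibitor genes 3 rose (camera adjusted p = 0.000201, adjusted p = 0.52 with an estimated correlation), with Cdkn1a, named after its values were seen, 40.6-fold higher (35.2 to 47). Apoptosis genes were mostly not called (4 of 29 rose, 2 fell, adjusted p = 0.562). Of 25 genes that respond to tissue dissociation, 5 rose and 3 fell (6 and 3 adjusted over the list alone, adjusted p = 0.562), and the heat shock gene Hspb1, also named after its values were seen, was 12.3-fold higher (10.6 to 14.2). None of the 6 sex-linked genes was called with either tool or at an unadjusted p under 0.05 (adjusted p = 0.647). The classes were defined on the same cells that were tested, here and in each comparison below, so the p-values are too small. In the Crect lacZ library the 12 ectoderm markers reached a median of 2.38% of their ectodermal level in mesenchyme-like cells. Free RNA and low expression in mesenchyme were not separated, and free RNA would make the folds too small.

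**Figure D2:**
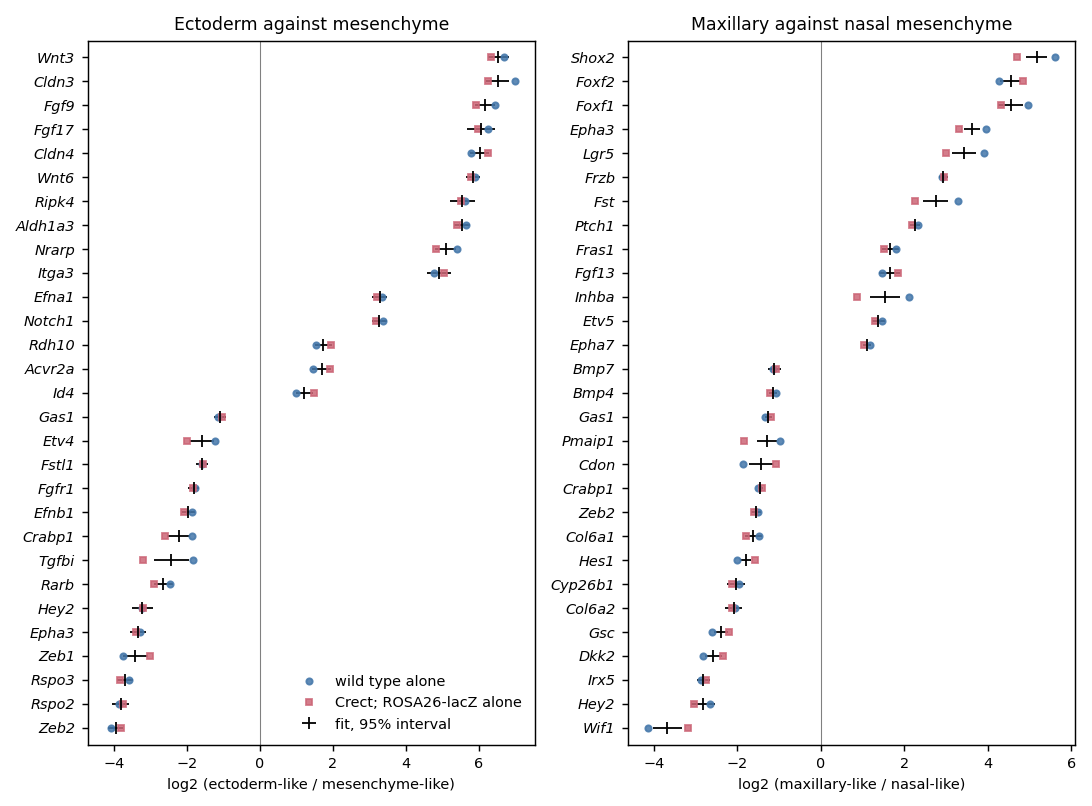
Log2 ratio of ectoderm-like to mesenchyme-like cells (left) and of maxillary-like to nasal-like mesenchyme (right) for genes that the rule named in each comparison, where circles give the ratio within the wild-type library, squares within the Crect; ROSA26-lacZ library, and the vertical ticks with horizontal bars the fitted value with its 95% interval. The rule asked for the same sign in both libraries, and their ratios lie on the same side of 0 for each gene. In order of the fitted value, the left side runs from Wnt3, with ratios of 6.68 and 6.33, to Zeb2, with -4.08 and -3.79.

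In periderm-like cells, against the rest of the ectoderm, Notch1 was 17.6-fold higher (95% interval 14.6 to 21.2) and its target Heyl 30-fold higher (15 to 60.2, adjusted p = 6.95e-20). The desmosomal plaque gene Pkp1 (ENSMUSG00000026413, chromosome 1, 135871395 to 135919207) was 26.3-fold higher (15.5 to 44.7, adjusted p = 2.1e-31), and the epithelial splicing regulator gene Esrp2 was 6.82-fold higher (5.21 to 8.94, adjusted p = 1.97e-41) in both libraries. Crispld2, a secreted protein gene linked to clefts, was 11.8-fold (7.18 to 19.3, adjusted p = 9.67e-21), Fgfr3 9.98-fold (5.73 to 17.4, adjusted p = 2.1e-14) and Cldn1 6.94-fold (4.60 to 10.5, adjusted p = 1.51e-18) higher. Aldh1a3 was 43.9-fold lower in periderm (33.5 to 57.5, adjusted p = 4.76e-157), the Wnt target and receptor gene Lgr5 6.64-fold lower (3.92 to 11.2, adjusted p = 6e-11) and the Hedgehog effector gene Gli3 4.29-fold lower (2.96 to 6.22, adjusted p = 6.13e-13). Fgf8 had 0 UMIs in periderm-like cells, at least 29.2-fold lower against a floor of 3 UMIs over both libraries, a call that DESeq2 did not make (adjusted p = 0.354). In all, 420 genes were called higher and 290 lower in periderm.

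Of 14 Notch pathway genes 6 rose and 3 fell in periderm, and of 38 adhesion genes 13 rose and 5 fell, with the same counts adjusted over the list alone. Both lists were higher (camera adjusted p = 7.75e-05 and 1.34e-05, adjusted p = 0.49 for each with an estimated correlation). Signalling lists were lower: 14 of 23 Fgf pathway genes fell and 1 rose (15 and 2 adjusted over the list alone), and 6 of 13 retinoic acid genes fell (6). Of the others, 14 of 49 Wnt pathway genes fell and 2 rose (15 and 2), 4 of 11 Hedgehog genes fell (5), and 7 of 30 Bmp and Tgf-beta genes fell and 1 rose (8 and 1). Their camera adjusted p-values were 3.01e-07, 1.82e-07, 0.00508, 0.00152 and 0.00171, and with an estimated correlation the adjusted p was 0.563 for the Wnt list and 0.49 for the others. Of 49 matrix and basement membrane genes 15 fell (16, with 1 higher, adjusted over the list alone), and of 52 patterning factors 11 fell and 6 rose; both lists were lower (camera adjusted p = 2.9e-05 and 0.00508, adjusted p = 0.49 for each with an estimated correlation). The ectodermal growth factor gene Pdgfc was 2.95-fold lower (2.42 to 3.60, adjusted p = 1.54e-24), and Tfap2c, a trophectoderm and skin transcription factor gene, was 2.77-fold higher (2.15 to 3.57). Clefting genes split (6 of 35 rose, 10 fell, camera adjusted p = 0.934). Of 22 dissociation genes 5 rose (camera adjusted p = 0.61), Hspb1 by 5.33-fold (4.54 to 6.25) and Klf4, which also acts in skin barrier formation, by 4.15-fold (2.95 to 5.84), both named after their values were seen. The comparison rests on 55 and 33 periderm-like cells. They were grouped and tested on the same data, and Notch1 was among their leading genes, so the p-values are too small. Its p-values use a spread taken from all genes, so they do not measure how well a single gene repeated between the libraries. DESeq2 called 209 genes higher and 73 lower (74.1% higher, against 59.2% with edgeR), and without the library term 264 and 124 were called.

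The sub-cluster named olfactory-like had high olfactory markers, at a mean of 0.956 of their highest level in any ectodermal sub-cluster. Among its 10 leading genes, neuronal markers outnumbered olfactory ones (6 against 1). Differences of neuronal cells and of olfactory epithelium were therefore not separated in this sub-cluster. Against the ectoderm other than periderm, its cells had more of the neural cadherin gene Cdh2, 3.64-fold (95% interval 2.84 to 4.65, adjusted p = 0.000372). They also had more of the transcription factor gene Ebf1 (ENSMUSG00000057098, chromosome 11, 44617317 to 45008091), 5.44-fold (4.25 to 6.96, adjusted p = 8.58e-05), and of the guidance receptor gene Ephb1, 3.33-fold (2.38 to 4.68), each in both libraries. The retinol uptake receptor gene Stra6 was 4.40-fold higher (3.2 to 6.05, adjusted p = 0.000649) and the retinol dehydrogenase gene Rdh10 3.35-fold higher (2.57 to 4.37, adjusted p = 0.000686). Perp, a desmosome gene, was 11.4-fold lower (7.92 to 16.5, adjusted p = 9.31e-05), Fgf8 8.05-fold lower (5.11 to 12.7, adjusted p = 0.000673) and Snai2 5.16-fold lower (3.23 to 8.25, adjusted p = 0.00243). Of 47 Wnt pathway genes 13 fell and 1 rose (16 and 2 adjusted over the list alone, camera adjusted p = 1.42e-11), of 35 clefting genes 7 fell and 1 rose (8 and 2, camera adjusted p = 0.000635), and of 32 Bmp and Tgf-beta genes 5 fell and 1 rose (7 and 2, camera adjusted p = 0.00415). With an estimated correlation the adjusted p was 0.961 for each of these lists. Of 13 retinoic acid genes 4 rose and 1 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.036, higher, adjusted p = 0.961 with an estimated correlation), although the median log2 change was -0.14 and the mean 0.14. Of 56 patterning factors 9 rose and 12 fell (11 and 14 adjusted over the list alone), a list lower in olfactory-like cells (camera adjusted p = 0.0407, adjusted p = 0.961 with an estimated correlation). In all, 94 genes were called higher and 64 lower, and this count moved with most settings, from 32 and 27 with equal numbers of cells to 188 and 130 with the gene lists among the clustering features. The comparison rests on 35 and 80 cells.

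Maxillary-like and nasal-like mesenchyme, named for the tissues on either side of the junction, were compared next. The maxillary-like class was 1 sub-cluster and the nasal-like class 5. Unnamed sub-clusters of 1296 and 1136 cells, with the maxillary marker Lhx8 among their leading genes, were in neither group. The folds therefore describe the named sub-clusters, not all maxillary and nasal tissue. Sub-clusters were formed on the same cells that were tested, so the p-values are too small. Shox2 and Epha3 were among the leading genes of the maxillary-like sub-cluster, so their high folds are no separate evidence for it. The homeobox gene Shox2 (ENSMUSG00000027833, chromosome 3, 66971727 to 66981771) was 36-fold higher in maxillary-like cells (95% interval 30.2 to 43, adjusted p = 1.2e-15). The Hedgehog-responsive forkhead genes Foxf1 and Foxf2 were 23.5-fold (19 to 29, adjusted p = 6.61e-14) and 23.4-fold (19.6 to 28, adjusted p = 4.99e-15) higher, in both libraries. The Iroquois gene Irx5 was 6.99-fold (6.30 to 7.76, adjusted p = 3.13e-15) and the homeobox gene Gsc 5.20-fold (4.63 to 5.85, adjusted p = 1.87e-13) lower in maxillary-like cells. Among Wnt modulators, Lgr5 was 10.8-fold (8.73 to 13.2, adjusted p = 3.22e-12) and the antagonist gene Frzb 7.62-fold (7.06 to 8.21, adjusted p = 6.22e-17) higher. The antagonist genes Wif1 and Dkk2 were 12.7-fold (9.95 to 16.2, adjusted p = 1.27e-11) and 5.94-fold (5.18 to 6.81, adjusted p = 5.81e-13) lower. Ptch1, a Hedgehog receptor and target gene, was 4.79-fold higher (4.39 to 5.22, adjusted p = 4.99e-15), and Epha3 was 12.3-fold higher (10.7 to 14.1, adjusted p = 4.49e-15). The retinoic acid catabolic enzyme gene Cyp26b1 was 4.09-fold (3.51 to 4.75, adjusted p = 5.2e-11), Bmp4 2.20-fold (2.05 to 2.36, adjusted p = 2.93e-12) and the Notch effector gene Hes1 3.48-fold (3.15 to 3.84, adjusted p = 8.26e-13) lower.

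By group, 5 of 14 Hedgehog pathway genes rose in maxillary-like cells and 3 fell, and 16 of 61 patterning factors rose and 11 fell, with the same counts adjusted over the list alone. Both lists were higher (camera adjusted p = 1.97e-06 and 0.00026, adjusted p = 0.613 for each with an estimated correlation). Of 47 Wnt pathway genes 5 rose and 10 fell (5 and 11 adjusted over the list alone), of 15 retinoic acid genes 2 rose and 2 fell, and of 12 Notch pathway genes 3 fell (4 adjusted over the list alone). The test placed these lists lower (camera adjusted p = 0.00729, 4.72e-05 and 0.000212, adjusted p = 0.613 for each with an estimated correlation), though the median log2 change of the retinoic acid list was -0.005. Of 36 Bmp and Tgf-beta genes 5 rose and 4 fell, and the test placed the list lower (camera adjusted p = 0.0124, adjusted p = 0.613 with an estimated correlation), with a median log2 change of -0.14 and a mean of 0.006. Matrix genes were lower (7 of 49 fell, 3 rose, camera adjusted p = 0.00846), Col6a2 by 4.24-fold (3.68 to 4.89), and so was the adhesion list (2 of 36 fell, camera adjusted p = 0.0358); the adjusted p was 0.613 for each with an estimated correlation. With edgeR and with DESeq2, 0 of 52 G2 and M phase genes passed the call, with 29 higher and 1 lower at an unadjusted p under 0.05, and the list was higher (camera adjusted p = 0.0034, adjusted p = 0.68 with an estimated correlation). In all, 187 genes were called higher and 207 lower (47.5% higher), against 88 and 62 with DESeq2 (58.7% higher) and 27 and 25 without the library term. A sub-cluster of the nasal-like class was led by Hey2, Smoc2 and Emx2.

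Endothelium-like cells, a tissue common to both prominences, were set against the mesenchyme around them. The Notch ligand gene Dll4 (ENSMUSG00000027314, chromosome 2, 119325784 to 119335962), active in arterial and tip cells, was 195-fold higher (95% interval 136 to 280, adjusted p = 1.39e-172) and the glycosyltransferase gene Mfng 195-fold higher (166 to 228) in both libraries. Tbx1 was 106-fold (87.3 to 129), the junction gene F11r 59.5-fold (51.5 to 68.6), the receptor gene Epha2 43.9-fold (30.8 to 62.5, adjusted p = 2.56e-94) and its ligand gene Efna1 35.7-fold (31.2 to 40.7) higher. The growth factor gene Tgfb1 was 39.4-fold (34.4 to 45.2), its receptor gene Tgfbr2 12-fold (10.1 to 14.2, adjusted p = 1.87e-168) and the Wnt and Norrin receptor gene Fzd4 7.66-fold (6.39 to 9.18, adjusted p = 2.78e-104) higher. Gas1 was 17.1-fold (14.6 to 19.9), Rspo3 16.2-fold (13 to 20.2, adjusted p = 1.37e-130), Dkk2 15-fold (11.9 to 18.8, adjusted p = 2.04e-116), Msx1 14.1-fold (12.3 to 16.1) and Gli2 7.65-fold (5.97 to 9.81) lower. Patterning factors were lower as a list (45 of 63 fell, 4 rose, camera adjusted p = 3.26e-11), and so were Wnt (28 of 50 fell, 4 rose, 1.09e-06) and Hedgehog genes (11 of 15 fell, 1 rose, 5.06e-05). The same held for Bmp and Tgf-beta (24 of 37 fell, 2 rose, 5.67e-05), retinoic acid (9 of 15 fell, 4.56e-05), Eph and ephrin (14 of 20 fell, 3 rose, 0.00118) and clefting genes (20 of 36 fell, 5 rose, 0.00124). The adjusted p was 0.393 for each of these with an estimated correlation, and each list had the same counts adjusted over the list alone. Notch genes were higher (8 of 16 rose, 4 fell, camera adjusted p = 0.00546, adjusted p = 0.406 with an estimated correlation), and so were dissociation genes (8 of 23 rose, 1 fell, camera adjusted p = 0.0185, adjusted p = 0.512 with an estimated correlation), with Junb, named after its values were seen, 32.1-fold higher (27.7 to 37.2). In all, 1406 genes were called higher and 1779 lower (44.1% higher), against 1273 and 1117 with DESeq2 (53.3% higher) and 1049 and 952 with equal numbers of cells (52.4% higher). As for periderm, the edgeR p-values use a spread taken from all genes, not from the single gene.

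The reporter design asks which cells express the ectodermal Cre and which have activated lacZ. Only the Crect lacZ gene table holds these transgenes. At a fixed depth of 3000 UMIs per cell, Cre was detected in 19.1% of ectoderm-like cells (143 of 747, 95% exact interval 16.4 to 22.2) and in 0.228% of mesenchyme-like cells (12 of 5253, 0.118 to 0.399). Within the ectoderm the share with Cre ran from 1.25% (1 of 80, 0.0316 to 6.77) in the olfactory-like sub-cluster to 32.1% (25 of 78, 21.9 to 43.6) in a basal surface-like one, at 15.8 and 106 CPM. In the same sub-clusters lacZ was detected in 5% (4 of 80, 1.38 to 12.3) and 6.41% (5 of 78, 2.11 to 14.3). Its levels there were 22.5 CPM (15.9 to 31) and 12.8 CPM (6.99 to 21.5), so the fall in Cre was not matched by lacZ. Cre was found in 0 of 118 endothelium-like and 0 of 136 erythroid-like cells, which allows shares of cells with a UMI at this depth of up to 2.54% and 2.21% (3 cells of the total) or 3.08% and 2.68% (exact upper limits). Without thinning it was found in 1 and 2 of these cells. The lacZ transcript was detected in 5.89% of ectoderm-like cells (44 cells, 4.31 to 7.83), 0.362% of mesenchyme-like cells (19 cells, 0.218 to 0.564), 2.54% of endothelium-like cells (3 cells, 0.527 to 7.25) and 0 of 136 erythroid-like cells, with the same limits. Without thinning the shares were 57% and 1.03% for Cre and 28.1% and 2.13% for lacZ in ectoderm-like and mesenchyme-like cells, whose median depths were 16540 and 17241 UMIs. In summed counts Cre reached 70.8 CPM (UMIs scaled to a common total per class) in ectoderm and 0.589 in mesenchyme, and lacZ 18.7 (16.4 to 21.1) and 1.34 (1.12 to 1.60). The mesenchymal level was 0.832% of the ectodermal one for Cre (0.622 to 1.09) and 7.18% for lacZ (5.75 to 8.93). Beside these, 12 ectoderm markers had a median of 2.38%, with single markers from 1.22% to 3.2%. In endothelium-like cells lacZ was found in 6.78% without thinning (8 of 118, 2.97 to 12.9) and reached 1.95 CPM (0.890 to 3.69), while with doublets kept it was found in 0% at 3000 UMIs. Cells were thinned in a separate random draw for that setting, so the change from 3 cells to 0% cannot be tied to the doublets.

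**Figure D3:**
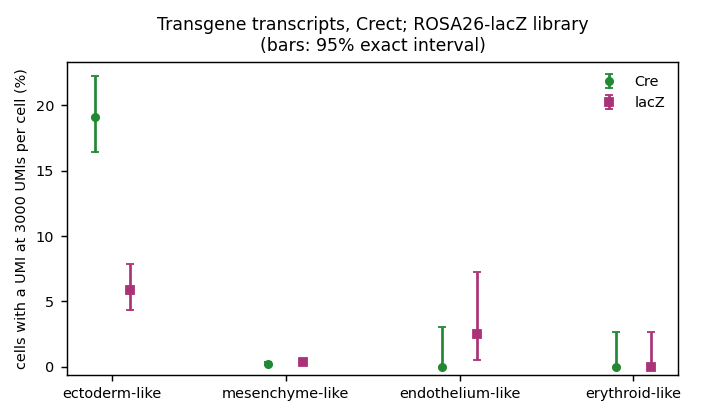
Share of cells (percent) with a UMI of Cre (circles) or lacZ (squares) after thinning to 3000 UMIs per cell in the Crect; ROSA26-lacZ library, by class, with 95% exact binomial intervals. Ectoderm-like cells stand at 19.1% for Cre and 5.89% for lacZ, and mesenchyme-like cells at 0.228% and 0.362%.

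Between the genotypes, the transcripts named by the size of their difference in both tissues were largely pseudogene-like, antisense and histone genes, and the comparison is of 2 libraries, not of the genotypes. Xist, expressed from the inactive X chromosome of female cells, was at 665 CPM in wild-type and 405 CPM in Crect lacZ mesenchyme, a ratio of 0.608 (95% counting interval 0.6 to 0.616), and the ectodermal ratio was 0.468 (0.453 to 0.484). The Y-linked Eif2s3y was higher, at 1.48 (1.41 to 1.56) and 1.47 (1.30 to 1.65), whereas Kdm5d was at 0.796 (0.734 to 0.863) and 0.856 (0.689 to 1.06). Ddx3y stood at 0.965 (0.915 to 1.02) and 1.34 (1.17 to 1.54), and Uty at 1.14 (1.06 to 1.23) and 1.48 (1.23 to 1.79), the last of these 0.908 in ectoderm after thinning. Tsix, which overlaps Xist on the other strand, stood at 0.697 (0.649 to 0.749) and 0.651 (0.542 to 0.780). The antisense gene BC023719, in the major histocompatibility region (chromosome 17, 36111426 to 36117121, build mm10), had 1 UMI in wild-type and 2120 in Crect lacZ mesenchyme, with a ratio of 1990 and a counting interval from 358 to 78800. It had 0 and 288 UMIs in ectoderm, at least 125-fold higher against a floor of 3 UMIs. Gm10260 (chromosome 13, 97760072 to 97760632) was 49.9 times (46.1 to 54) and 44.1 times (37.7 to 51.8) higher, and the processed pseudogene Gm10709 42 times (39.8 to 44.3) and 35.2 times (31.7 to 39.2). The processed pseudogene Gm5900 was 37.3 times (29.6 to 47.5) and 44.9 times (25.4 to 87.7; 105 times after thinning), and Gm8797 15.6 times (15 to 16.3) and 15.5 times (14.1 to 17.1), higher in mesenchyme and ectoderm. The zinc finger gene Zfp955b (chromosome 17, 33289544 to 33307241) was 7.84 times (6.33 to 9.81) and 8.60 times (4.88 to 16.5) higher in wild type. The linker and core histone genes Hist1h1b, Hist1h1e, Hist2h2ac and Hist1h1a were higher in wild type as well, by 7.25 times (7.04 to 7.47), 6.47 times (6.24 to 6.71), 5.67 times (5.30 to 6.07) and 6.86 times (6.29 to 7.50) in mesenchyme and by 6.49, 6.35, 6.81 and 5.25 times in ectoderm. The histone gene Hist1h2ap, named after its values were seen, went the other way, 3.74 times (3.66 to 3.83) and 2.74 times (2.57 to 2.93) higher in Crect lacZ. Counts of pseudogenes, of multicopy histone genes and of antisense genes are uncertain, since reads can be shared with near-identical or overlapping genes and the strand setting of the counting is not given in the sources used here.

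Several genes were named after their values were seen. The growth factor gene Igf2 was 2.50 times (2.42 to 2.58) and 2.84 times (2.72 to 2.96) higher in wild-type mesenchyme and ectoderm, and the haemoglobin gene Hba-a2 3.12 times (3.05 to 3.2) and 2.84 times (2.67 to 3.03). Hba-a2 stood at 288 and 263 CPM there against 63770 CPM in wild-type erythroid-like cells, with ectoderm to mesenchyme ratios of 0.912 and 1 in the 2 libraries, and is read as background. The class I histocompatibility gene H2-K1 was 21.3 times (13.9 to 34.4) and 7.94 times higher in Crect lacZ, from 22 and 38 wild-type UMIs, and the ectodermal ratio was 24 after thinning. The transcription factor gene Sp8 was 3.19 times (2.79 to 3.65) higher in Crect lacZ ectoderm. It was higher in both tissues, with log2 ratios of 2.33 in mesenchyme and 1.67 in ectoderm. The immediate early gene Egr1 was 4.56 times (3.60 to 5.83) and 3.22 times (2.48 to 4.21) higher in Crect lacZ mesenchyme and ectoderm. The chondrogenic regulator gene Sox9 was 3.18 times (3.04 to 3.33) higher in Crect lacZ mesenchyme and 1.57 times without the chondrogenic-like cells. Wild-type ectoderm had its fullest cluster led by Tfap2b and Wnt6 (371 cells), and Crect lacZ ectoderm had its fullest cluster led by Aldh1a3 and Six3 (341 cells). These 2 counts were made before a sub-cluster was taken out of the ectoderm. In mesenchyme the fullest clusters were led by Cxxc4 and Rerg in wild type (713 of 6150) and by Rpgrip1 and Notch2, with low UMI counts, in Crect lacZ (484 of 5253).

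**Figure D4:**
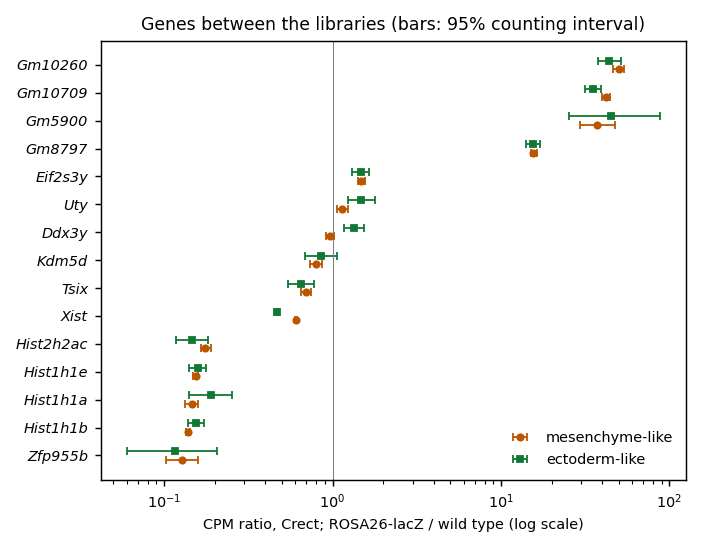
Ratio of CPM between the Crect; ROSA26-lacZ and the wild-type library (log axis) in mesenchyme-like (circles) and ectoderm-like cells (squares) for the sex-linked genes and the genes of the size rule, with 95% counting intervals and without BC023719, whose ectodermal wild-type count was 0. The ratios in mesenchyme-like cells run from 49.9 for Gm10260 to 0.128 for Zfp955b.

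The last question was whether cycling differed between classes. At 3000 UMIs per cell, the proliferation gene Mki67 was detected in 37.2% of wild-type and 25.7% of Crect lacZ mesenchyme-like cells, 28.7% and 18.2% of ectoderm-like cells, 31.9% and 16.9% of endothelium-like cells and 56.9% and 44.9% of erythroid-like cells. The topoisomerase gene Top2a was detected in 61.7% and 53.1%, 47.9% and 42.6%, 53.7% and 39.8%, and 45.7% and 38.2% of the same classes. In CPM, Mki67 fell from mesenchyme to ectoderm within each library (215 and 139 in wild type, 121 and 83.4 in Crect lacZ), and so did Top2a (705 and 405, 467 and 273). No test was made, and without thinning the order of the libraries turned for Top2a in ectoderm-like cells (70.2% in wild type and 72.6% in Crect lacZ). Unthinned shares rise with depth, and the median depth of these cells was 14959 UMIs in wild type and 16540 in Crect lacZ. In CPM, which is scaled for depth, Top2a kept the order of the thinned shares (405 and 273). Every cell kept was deeper than 3000 UMIs, so 0 cells were left out by thinning. The median gene stood at a log2 ratio of -0.09 between Crect lacZ and wild type in mesenchyme and in ectoderm, -0.13 in endothelium and -0.03 in erythroid-like cells.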

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

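The tests of free RNA as the source of lacZ counts, of the border of the dissected tissue, and of all explanations for genes that differ between the libraries were chosen only after the result was seen. The other 4 tests were written before, except that the p-value for the lacZ shares was added after. In the comparison of ectoderm with mesenchyme, Bmp3 had a log2 ratio of -1.28 in the wild-type and 1.22 in the Crect lacZ library (5 and 18 ectodermal UMIs), and Ebf2 -1.18 and 1.73 (5 and 57). In the comparison of periderm with the other ectoderm, Cdc6 stood at -1.15 and 1.08 (10 and 24 periderm UMIs) and Osr2 at -1.43 and 1.77 (3 and 18). These 4 genes stood out because their libraries moved in opposite directions. The difference was not tested, the counts are small, and none of the 4 was called.

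The lacZ transcript was found in mesenchyme-like cells of the Crect lacZ library, at 7.18% of its ectodermal level (5.75 to 8.93). It was not particular to mesenchyme among the other classes. Endothelium-like cells had 1.95 CPM (0.890 to 3.69, from 9 UMIs), against 1.34 CPM (1.12 to 1.60) in mesenchyme-like cells. Erythroid-like cells had 0 UMIs (up to 1.62 CPM). Free RNA from ectoderm is argued against as the whole source, since Cre reached 0.832% and the highest of 12 ectoderm markers 3.2%. Droplets with an ectodermal and a mesenchymal cell are argued against as well, because lacZ-positive mesenchyme-like cells lay 0.221% of the way to an equal mixture (-1.04 to 1.86). A few mesenchyme-like cells with lacZ at the ectodermal level stay open as the source. Of positive cells 10.7% had 2 or more UMIs (12 of 112, 5.66 to 18), above the 1.36% that a single rate gives. This interval lay under the 19% of ectoderm, the bound written before, but that bound left out the spread of the ectodermal share (14 to 25), which overlaps it (Fisher's exact p = 0.0574). Several sources together, and earlier activity of Cre in these cells, were not tested and stay open.

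Of 556 chondrogenic-like cells, 529 (95.1%, 93 to 96.8) came from the Crect lacZ library. A shift of the whole library stays open. The 10 leading genes had a median log2 ratio of 0.61 in the other mesenchyme-like cells (single genes from -0.10 to 0.98), under the bound of 1 written before. But they were chosen for this pattern, clustering had taken out the cells highest in them, and 8 of the 10 were higher in Crect lacZ. Cells of 1 embryo are argued against, since both Xist (1.13, 1.09 to 1.17) and the Y-linked genes (1.16, 1.08 to 1.24) were present at or above the level of the other mesenchyme. A different border of the dissected tissue may be a source, and 2 of 21 other sub-clusters were also uneven, though less so (75.2% and 78.9% of their library-adjusted share in that library), which leaves it open. The first of these is the olfactory-like one, with mostly neuronal markers among its leading genes. The second is an unnamed ectodermal one with a low median depth, 0.433 times that of its library. Its leading genes included Gm8797 and Gm10320, which were higher in Crect lacZ in both tissues, so its unevenness cannot be read as one of tissue. The genotype is confounded with the library and stays open, untested.

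Some genes differed in the same direction between the libraries in both mesenchyme and ectoderm. Pseudogenes made up 5.93% of them (2.59 to 11.3), against 0.395% of the genes compared, and they were 19.4% of those higher in Crect lacZ (8.19 to 36) and 1.01% of those lower. For the pseudogenes, nearly all of them higher ones, the sharing of reads between near-identical copies is a candidate explanation. Their share does not tell why such sharing would differ between the libraries. Free RNA from erythroid cells is argued against as the whole cause, since 2.22% were haemoglobin genes, and so is a single chromosome segment of another strain, since, with pseudogenes left out, the fullest chromosome (11) held 13.8% of those higher in Crect lacZ (3.89 to 31.7), and with them chromosome 17 held 13.9%. A segment of another strain around the histocompatibility genes of chromosome 17 stays open for the genes there, which made up 3.70% (1.21 to 8.43) against 1.24% of the genes compared. The genotype, the pools of embryos and the processing of each library, whose gene tables differ by the Cre and lacZ entries, stay open, untested.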

How the results depend on the processing

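Tests without clusters of low UMI counts, without chondrogenic-like cells and without olfactory-like cells were chosen only after the result was seen. For 163 named genes, 1640 values under the settings that keep both libraries stayed on the same side of the call, 49 lost the call and 0 reversed. With 1 library left out, 191 folds moved by more than the standard error of the fit and 130 did not, and 0 reversed. The naming rule had required the same sign in both libraries, so for genes it named this 0 is no check of direction. Counts of calls have no such value. The higher gene minimum changed no count of calls, and the lower was run only for cells kept and class shares.

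For the values below the cause was not tested, unless it is stated. Calls higher and lower in periderm were 209 and 73 with DESeq2, 264 and 124 without the library block and 173 and 110 with equal numbers of cells. For olfactory-like cells they were 59 and 36 with DESeq2, 153 and 122 without the low-count filter, 53 and 37 without the block, 144 and 100 with all classes in 1 fit, 188 and 130 with lists as clustering features, 32 and 27 with equal cells and 143 and 98 at sub-cluster resolution 0.4. For maxillary-like cells they were 88 and 62 with DESeq2, 27 and 25 without the block, 106 and 116 with all classes in 1 fit and 103 and 116 with equal cells. In ectoderm, 1026 were higher with all classes in 1 fit and 597 lower without the block. In endothelium, 1273 were higher and 1117 lower with DESeq2, and 1049 and 952 with equal cells. Equal numbers of cells leave fewer counts per sum, which lowers what can be called.

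With an estimated correlation 0 gene lists passed camera in each of the 5 comparisons. For olfactory-like cells 3 lists passed with all classes in 1 fit, 3 with lists as clustering features and 2 at sub-cluster resolution 0.4, against 5. For maxillary-like cells 4 passed without the low-count filter, 1 with all classes in 1 fit and 3 at sub-cluster resolution 0.4, against 9.

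With doublets kept there were 7909 wild-type and 6687 Crect lacZ cells, 78.5% of wild-type cells were mesenchyme-like, and lacZ was found in 0% of endothelium-like and 0% of crest glia-like cells. These cells were thinned in a separate random draw, so the 0% cannot be tied to the doublets. At resolution 2.0, 3.67% of wild-type cells were erythroid-like and 10.4% of Crect lacZ cells ectoderm-like. Unthinned cells are deeper, which raises shares by construction: Cre reached 1.03% of mesenchyme-like and 57% of ectoderm-like cells, and lacZ 2.13% and 28.1%. Mki67 reached 70.8% and 64.9% (wild type and Crect lacZ) in mesenchyme, 61.1% and 50.9% in ectoderm, 81.9% and 76.3% in endothelium and 94.4% and 74.3% in erythroid-like cells. Top2a reached 82.7% and 81.6%, 70.2% and 72.6%, 91.2% and 88.1%, and 88.8% and 72.8%.

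For Crect lacZ against wild type within a class, the median log2 ratio was -0.005, -0.033, -0.04 and -0.106 with TMM scaling in mesenchyme, ectoderm, endothelium and erythroid-like cells, and -0.106, -0.151 and -0.012 with thinned cells in the last 3. Of the ratios between the libraries, 17 left their counting interval without reversing with thinned cells and 8 with TMM scaling, among them Gm5900 in ectoderm (105, from 44.9, thinned). With thinned cells 4 more ratios of Crect lacZ over wild type left it and fell on the other side of 1: Eif2s3y in erythroid-like cells (0.853, from 1.61), Uty in ectoderm (0.908, from 1.48), Gm5900 in erythroid-like cells (0, from 61.1) and Zfp955b in endothelium (1.83, from 0.0775). The last 2 rest on 1 and 20 and on 34 and 2 UMIs (wild type and Crect lacZ) before thinning, too few to read a direction, and the 0 has no floor. Depth limits shares of cells with a transcript, as Cre in ectoderm-like cells (57% unthinned, 19.1% at 3000 UMIs). Periderm-like and olfactory-like cells numbered 33 and 35 in the smaller library of each.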

Other observations

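Both comparisons below were chosen only after the result was seen and were run under no alternative setting except camera's estimated correlation, with which 0 lists passed (lowest adjusted p = 0.688 and 0.492). An unnamed ectodermal sub-cluster of 77 wild-type and 27 Crect lacZ cells, led by Col9a1, Dkk4 and Adamts9, had 15.3-fold higher Dkk2 (95% interval 12.1 to 19.4), 9.28-fold higher Dusp6 (7.87 to 11) and 8.18-fold higher Etv4 (6.04 to 11.1) than the rest of the ectoderm, by edgeR. The cell cycle inhibitor gene Cdkn1c was 4.10-fold higher (3.71 to 4.53). Fgf9 was 18.2-fold (12.7 to 26) and Wnt4 5.82-fold (4.47 to 7.58) lower. Of 52 G2 and M phase genes 10 were lower, and of 42 S phase genes 2 (camera adjusted p = 2.49e-25 and 8.96e-08, adjusted p = 0.688 for each with an estimated correlation). Dkk2 and Dusp6 were themselves among the leading genes of this sub-cluster in the same cells, so their high folds are no separate evidence. The intervals use a spread taken from all genes, not from the single gene.

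A second unnamed sub-cluster of 58 wild-type and 58 Crect lacZ cells, led by Gad2, Fst and Cdkn2a, had 20.3-fold higher Cdkn2a (14.6 to 28.3), 9.41-fold higher Inhba (6.97 to 12.7) and 3.27-fold higher Wnt5a (2.66 to 4.01). The junction gene Cldn3 was 7.48-fold lower (5.06 to 11). Cdkn2a and Inhba were among the leading genes of this sub-cluster in the same cells, so their high folds are no separate evidence.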
